A study of Mus musculus with 3 samples.

How the data were processed

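RNA from mouse trophoblast stem cells of the 129/SvEv strain was measured in 3 libraries, 1 per group. WT_vector holds wild-type cells with the empty pLKO vector. KI4_vector holds cells with the MAP3K4 K1361R knock-in and the same vector. KI4_HDAC6sh holds knock-in cells with a short hairpin against Hdac6. The hairpin carries a different number in the sample title than in the name of the deposited data, so it is called the Hdac6 hairpin here. Groups were taken from the sample titles.

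Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as single reads of 75 bases, 12 to a run. The submitters' processing notes name RSEM without a version, SAMtools 1.2, Picard 1.88 and the mm9 build, with no order or role. Further settings are not given in the sources used here, including whether counting used the strand. Each library has 21705 genes. The authors deposited an expected count per gene, which is an estimate of reads and was not always whole. Of the expected counts above 0 in WT_vector, 87.4% were exactly whole. The authors also deposited TPM and FPKM values, which divide by transcript length and depth. The TPM values of the genes used sum to 860778 in WT_vector, 867124 in KI4_vector and 856715 in KI4_HDAC6sh, less than TPM values of a whole library sum to, so part of each library lies in features not used here. The last deposited column is a normalised signal, called normalised count here. From the values, it equals the expected count divided by 1 factor per library and multiplied by 1000. That factor lay within 0.132% of the upper quartile of expected counts above 0 in each library. Such scaling sets 1 point of each distribution equal and does not remove differences that follow chromosomes or culture.

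The normalised count was used for all main results. One ppm was set as the mean column total divided by 1e6, which is 14.32 normalised counts. A difference is log2 of the ratio of normalised counts after adding 1 ppm to each, which understates the difference of low genes. Genes with a mean of at least 5 ppm over the 3 libraries were kept, which left 9950. A gene was counted as higher or lower at a difference of at least 1, which is 2-fold. With 1 library per group there is no replicate check on any difference, and no test between groups or p-value is given. Folds of named genes are ratios of normalised counts without the added ppm. Their 95% intervals are exact Clopper-Pearson intervals from expected counts rounded to whole numbers. Where a library had 0 counts, the fold was computed against 3 counts in that library and is given as "at least". Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

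There were 36 gene lists, covering epithelial, mesenchymal and trophoblast genes, signalling, metabolism, chromatin, other cell types and controls. For each list the median difference of its tested members is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. The lists, thresholds, alternatives and naming rule were fixed before the data were examined. Named genes are Map3k4 and Hdac6, the 12 highest and 12 lowest genes of the first 2 comparisons among genes with assigned names, and up to 4 members per list with the largest absolute difference. For genes that moved back, the rule named the 10 with the largest first difference in each direction. Genes named outside that rule are said to be so where they appear.

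Both main comparisons share KI4_vector. Unchanged libraries were therefore simulated in 100 draws with counting noise alone and with added coefficients of variation of 0.1, 0.2 and 0.4. The count of 2-fold genes was tested on simulated data built from KI4_vector against WT_vector. With counting noise alone over 9942 genes, genes set 4-fold higher or lower were each counted in 100% of cases. Those set 2-fold higher were counted in 40% and those set 2-fold lower in 34%, and 0 unchanged genes were counted. With a coefficient of variation of 0.2 over 9938 genes, these shares were 94% and 98% at 4-fold and 52% and 42% at 2-fold, and 167 unchanged genes were counted. The counting intervals then held the set fold for 28% of the genes set 4-fold higher, against 90% with counting noise alone. Gene positions come from an annotation of the same mouse assembly, NCBIM37, made by GENCODE. Of the genes kept, 9781 (98.3%) matched a single gene of that name. Map3k4 has more than 1 model of its name there and was left out of the results by chromosome.

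Alternatives were other added constants, other filters, other scalings, the other deposited columns, other thresholds, unmatched random lists, and leaving out gene models without an assigned name. Differences centred on each chromosome's median, results without chromosomes 1, 8, 9, 19, X and Y, and the rule for long segments were chosen after seeing the data. A segment is a run of at least 20 Mb in which the running median of 25 tested genes stays beyond 0.2 in size. Computation used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Mitochondrially encoded genes, Hba-a1 and Hmgcs1 were not analysed here.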

Results

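Gene expression was measured in mouse trophoblast stem cells, the precursors of the placental trophoblast, kept in the stem state with FGF4 and heparin. MAP3K4 is a kinase upstream of the p38 and JNK pathways, and the K1361R allele makes it kinase-inactive. HDAC6 is a deacetylase that acts on tubulin and other proteins. The series addresses how MAP3K4 activity bears on chromatin regulators and on epithelial and mesenchymal states. There was 1 library each of wild-type cells with empty vector (WT_vector), knock-in cells with empty vector (KI4_vector) and knock-in cells with the Hdac6 hairpin (KI4_HDAC6sh). Total expected counts were 16391401, 16683161 and 17201853 in that order, and 14330, 14544 and 14535 genes were above 0.

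Hdac6 (X, 7507246 to 7525015, minus strand) had 3229 normalised counts in WT_vector, 6315 in KI4_vector and 230 in KI4_HDAC6sh. It was 27.4-fold lower in KI4_HDAC6sh than in KI4_vector (95% counting interval 24.3 to 31.1) and 14.0-fold lower than in WT_vector (12.4 to 15.9). It was 1.96-fold higher in KI4_vector than in WT_vector, whose level was 0.511 times that of KI4_vector (0.491 to 0.532). The 307 genes tested on its chromosome had a median difference of 0.51 in that comparison. Map3k4 had 1186, 1050 and 1067 normalised counts, a ratio of 0.885 in KI4_vector against WT_vector (0.819 to 0.957). The knock-in is a change of a single residue, so this level does not check the label. The models of that name lie on chromosome 17 of mm9, at 12420489 to 12511614 on the minus strand and at 12425347 to 12464050 on the plus strand, and reads from them could be split or pooled.

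**Figure D1:**
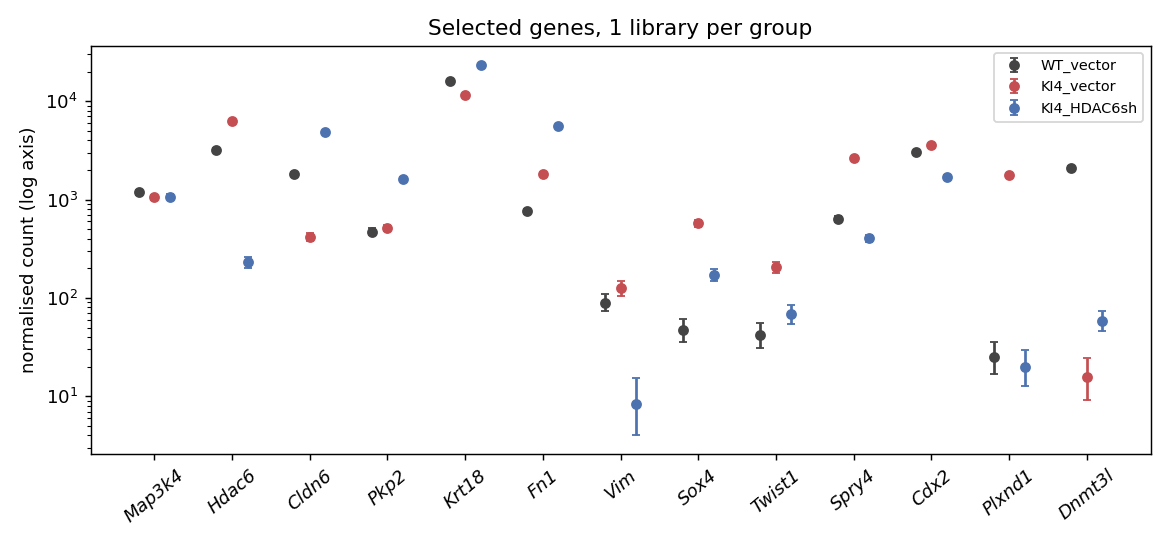
Normalised counts (log axis) of 13 genes in the 3 libraries, 1 point per library, with exact 95% Poisson intervals for counting error only. Hdac6 is lowest in KI4_HDAC6sh at 230, and Cldn6 is lowest in KI4_vector at 416 and highest in KI4_HDAC6sh at 4808.

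The first comparison, KI4_vector against WT_vector, concerns the kinase-inactive allele. Of 9950 genes tested, 543 were higher and 244 lower by at least 2-fold, and 91 and 48 by at least 4-fold. The median difference was 0.07, and 76.7% of genes lay within 1.5-fold. Higher genes made up 69.0% of the 2-fold genes, and 57.6% under median-of-ratios scaling, which moved the median of all genes by -0.10. Plxnd1, a semaphorin receptor (6, 115904829 to 115945023, minus strand), was 70.3-fold higher (48.8 to 105), and Fmr1nb 75.3-fold (42.9 to 146). Tcf15, a basic helix-loop-helix factor, was 49.1-fold higher (31.9 to 79.7), and Pcmtd2, at 0 in WT_vector, was at least 151-fold higher. Ctsc, Trib2, Gpc4 and Rnf17 were 20.4-fold, 15.1-fold, 14.8-fold and 17.6-fold higher. Fam111a, Lipa, Bhlhb9 and Aim2 were also among the 12 highest, with 7, 7, 18 and 4 expected counts in WT_vector.

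Among the lowest genes, the imprinted noncoding RNA H19 (7, 149761434 to 149764048, minus strand) had 51784 expected counts in WT_vector, 38 in KI4_vector and 30 in KI4_HDAC6sh. It was 1360-fold lower in KI4_vector (991 to 1922). Dnmt3l, a cofactor of de novo DNA methylation, was 134-fold lower (84.9 to 227), with 2091, 15.6 and 58.6 normalised counts. Tmem59l and B3gnt3 on chromosome 8 were 272-fold and 73.1-fold lower. Hspb8 and Zfp512, at 0 in KI4_vector, were at least 223-fold and at least 132-fold lower, and Zfp26 was 119-fold lower (46.0 to 437). Xlr5b was at least 123-fold lower, but like Xlr5a it belongs to a family of near-identical copies on the X chromosome, so its reads are uncertain.

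Genes of the Y chromosome were nearly absent from both knock-in libraries. Ddx3y had 2493 expected counts in WT_vector, 0 in KI4_vector and 2 in KI4_HDAC6sh, and Uty had 953, 0 and 2. Eif2s3y had 267, 0 and 0. Xist, too low to be tested and named after its values were seen, had 3, 8 and 0. Adjacent genes on chromosome 9 showed the same. Rhoa, a small GTPase that organises actin (9, 108208536 to 108240270, plus strand), had 5220, 0 and 5 expected counts and was at least 1737-fold lower in KI4_vector. Amt had 440, 0 and 0, Nicn1 317, 0 and 1, and Tcta 36, 0 and 0. Nicn1 and Tcta were named after their values were seen, as neighbours of Rhoa and Amt.

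**Figure D2:**
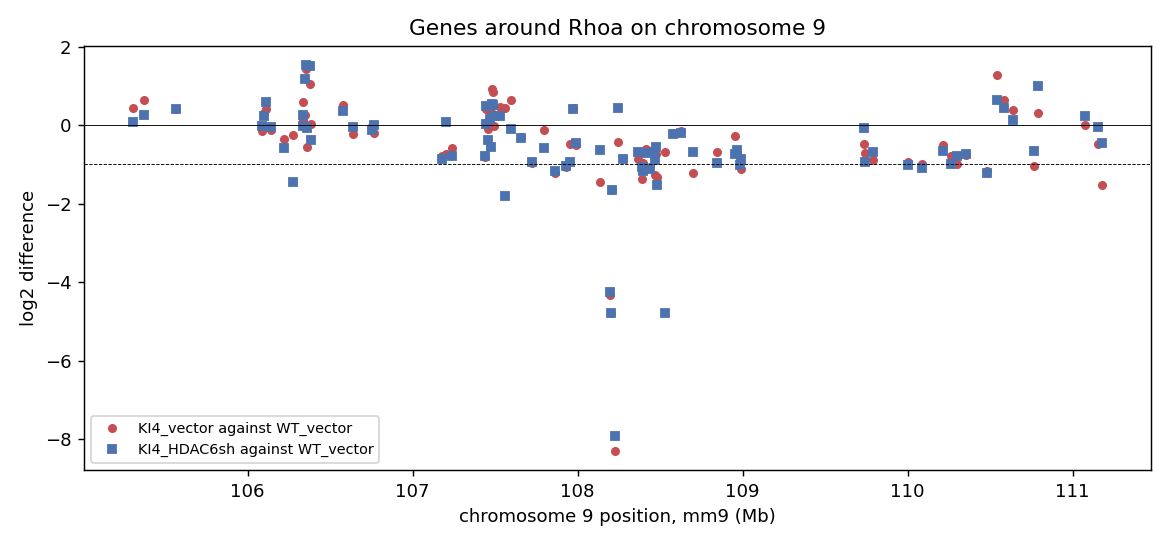
Log2 differences of the tested genes and Tcta around Rhoa, by position on chromosome 9 of mm9 in Mb, for both knock-in libraries against WT_vector. The lowest points are Rhoa at -8.30 and -7.93, and the dashed line marks a difference of -1.

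Whole chromosomes and long segments also differed between the cultures. In KI4_vector against WT_vector the median of chromosome 1 lay -0.47 from that of the other autosomes and that of chromosome 8 lay -0.48 from it. Within chromosome 2, 295 genes from 90.9 to 155 Mb had a median of -0.39. On chromosome 11, 138 genes from 3.81 to 49.1 Mb had a median of -0.43 and 207 genes from 62.1 to 84.6 Mb one of 0.61, so the chromosome's own median of 0.24 hides both. On the X chromosome, 103 genes from 7.40 to 67.7 Mb had a median of 0.64 and 140 from 71.7 to 161 Mb one of 0.63. Parts of chromosomes 4, 6, 9, 13, 15 and 16 had medians between 0.22 and 0.40. They held 15 to 61 genes, and the part of chromosome 16 held fewer than the 25 of the running median. What random order of genes would give was not computed for segments. Median-of-ratios scaling moved the median of all genes by -0.10, so the smallest of these medians depend on the scaling. Chromosome 19 showed no such shift here, at 0.00, but lay 0.53 above the other autosomes in KI4_HDAC6sh against KI4_vector, where 56 genes of the X chromosome from 90.6 to 131 Mb had a median of -0.77. Differences of genes on these segments carry such shifts.

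**Figure D3:**
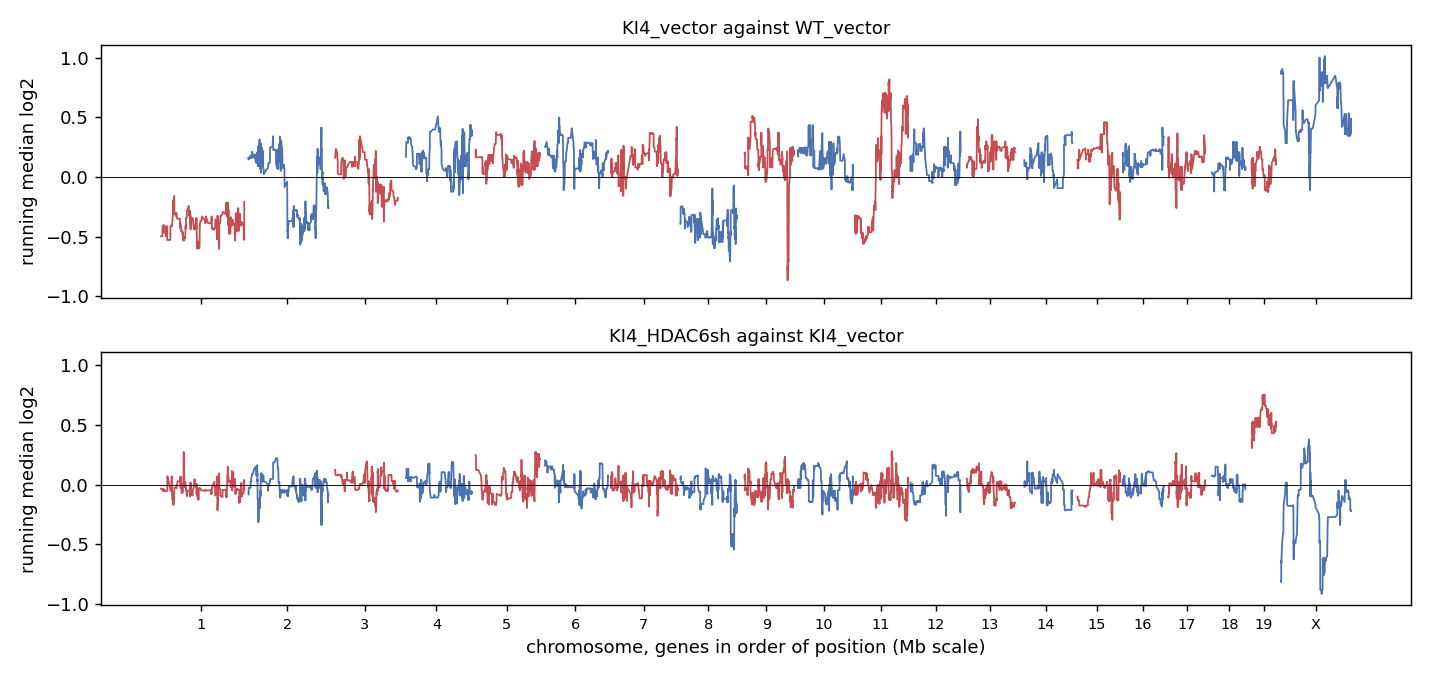
Running medians over 25 tested genes along chromosomes 1 to 19 and X (log2 difference, genes by position in Mb, alternating colours by chromosome), for KI4_vector against WT_vector above and KI4_HDAC6sh against KI4_vector below. Chromosomes 1 and 8 lie below 0 in the upper panel and chromosome 19 lies above 0 in the lower.

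Of 35 gene lists with at least 3 tested members, 8 had medians above and 6 below the central 95% of random lists in KI4_vector against WT_vector. Lists of unrelated genes would give 0.875 on each side. Members of a list can move together and some lists share members, so these numbers are not a test. After subtracting each chromosome's median, 10 of these 14 lists stayed outside on the same side, and those that did not were the heat shock, p53, ribosomal protein and Y-linked lists. Feedback targets of FGF and ERK signalling had a median of 0.79 (percentile 100), with 4 of 13 tested members 2-fold higher. Spry4, an inhibitor of this pathway, had 632 normalised counts in WT_vector and 2633 in KI4_vector, Dusp6 differed by 1.47 and Etv5 by 1.34. Cholesterol synthesis genes had a median of -0.59 (percentile 0), with 4 of 15 members 2-fold lower, among them Mvd and Sqle, both at -1.54, and Sc4mol at -1.44. Mvd and Sc4mol lie on chromosome 8. Unfolded protein and amino acid response genes had a median of -0.45 (percentile 0.03), with 4 of 14 members 2-fold lower and 1 higher. Chac1 differed by -2.53, Herpud1 by -1.71 and Trib3 by -1.46, and Phgdh, an enzyme of serine synthesis, was higher, at 1.31. Chac1 and Trib3 lie in the segment of chromosome 2 and Herpud1 on chromosome 8. Hypoxia and glycolysis genes had a median of 0.41 (percentile 99.95), with Egln3 at 2.55 and Pdk1 at 2.15. Their median was 0.23 (percentile 99.41) after subtracting each chromosome's median. Proliferation genes had a median of -0.31 (percentile 0.04), and 0 of 22 members were 2-fold different. Proteases of invasion, a list that also holds protease inhibitors and a receptor, had a median of 0.48 (percentile 99.22). Of its 13 tested members 3 were 2-fold higher, among them Plau at 1.87 and Mmp9 at 1.46.

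Desmosome and keratin genes had a median of -0.25 (percentile 2.32, and 2.61 among unmatched random lists, inside the central 95%), with 1 of 11 tested members 2-fold different, Jup at 1.07. Epithelial adhesion genes had a median of -0.14 (percentile 4.66). Among them the tight junction gene Cldn6 was 4.36-fold lower (3.95 to 4.83), Cgn differed by -1.03 and Cldn3 by 1.74. Cdh1, the E-cadherin gene, was named after its values were seen and had 26044, 23592 and 22905 normalised counts in the 3 libraries. Transcription factors of epithelial-mesenchymal transition had a median of 0.28 (percentile 80.4), with 4 of 10 tested members higher and 2 lower. The other 7 of the 17 members were too low to be tested, among them Snai2, Zeb1, Zeb2 and Twist2, named here outside the naming rule. The tested members include Id1, Id2 and Id3. Sox4 had 47.4 normalised counts in WT_vector and 571 in KI4_vector, Twist1 had 42.3 and 206, and Id1, in the segment of chromosome 2, differed by -2.16. Mesenchymal markers had a median of 0.22 (percentile 92.0), with Itgb3 at 616 normalised counts in WT_vector and 3549 in KI4_vector, Sparc at 1.39, Fn1 at 1.25 and Cyr61 at -1.24. Trophoblast stemness genes had a median of 0.00 (percentile 49.7), which was below 0 under other scalings, with Rhox9 at -3.94 and Bmp4 at 1.15.

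**Figure D4:**
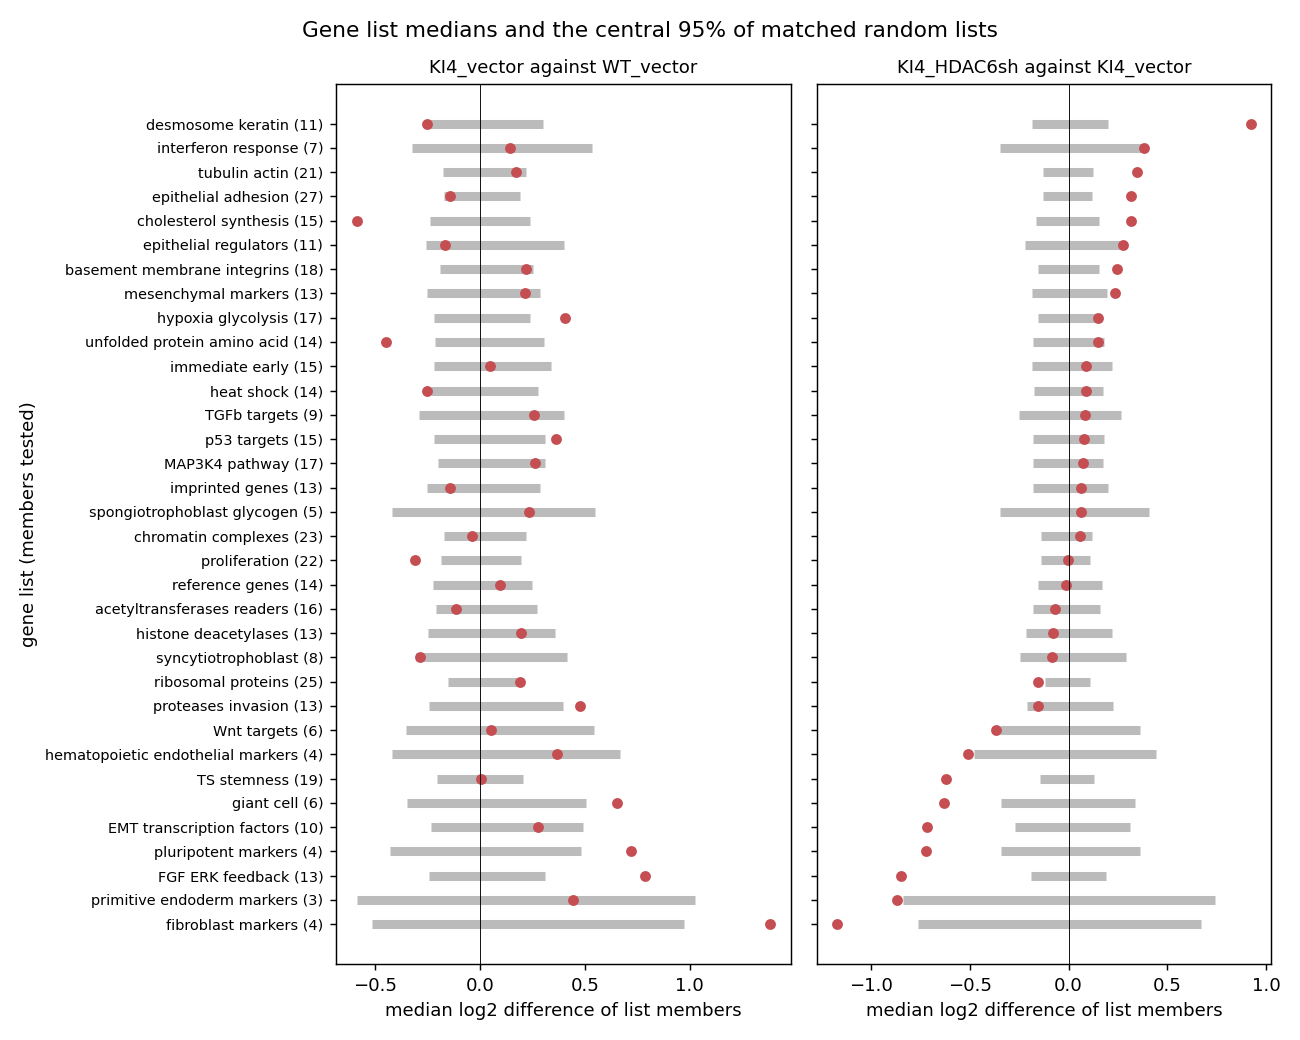
Median log2 difference of each list's tested members (points) in the first comparison (left) and in KI4_HDAC6sh against KI4_vector (right), with the central 95% of matched random lists as grey bars and the number of members tested in parentheses. The Y-linked list is left out for scale. Desmosome and keratin genes lie at -0.25 on the left and 0.92 on the right.

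The second comparison, KI4_HDAC6sh against KI4_vector, concerns the hairpin in knock-in cells. Of the genes tested, 301 were higher and 404 lower by at least 2-fold, 54 and 119 by at least 4-fold, and 82.9% lay within 1.5-fold. Maoa was 110-fold higher (42.8 to 407), and Zfp280c and Phka1, at 0 in KI4_vector, were at least 112-fold and at least 96.2-fold higher. Steap2 was 73.6-fold, Fndc3c1 54.4-fold and Fhl1 25.6-fold higher. The glucose transporter gene Slc2a3 was 15.4-fold higher (13.7 to 17.2), Cldn6 11.6-fold (10.5 to 12.7), and Tacstd2 11.9-fold (9.40 to 15.2). The receptor gene Csf1r had 92.5 and 1017 normalised counts. Papss2, on chromosome 19, and Dcaf12l1 were 12.5-fold and 13.5-fold higher. Of these 12 genes, Maoa, Zfp280c, Phka1, Fndc3c1, Fhl1 and Dcaf12l1 are on the X chromosome. Besides Hdac6, the lowest genes included Tnfrsf1a, 601-fold lower (205 to 2919) with 3 expected counts left, and Plxnd1 and Tcf15, 87.5-fold and 152-fold lower. Fmr1nb, with 3 expected counts left, was 311-fold lower (106 to 1509). Trim32 was 750-fold lower (134 to 29658) with 1 expected count left, and Pvrl1, at 0, was at least 108-fold lower. Serpinh1, a collagen chaperone, was 23.4-fold lower (20.1 to 27.3). Tex13, also with 3 expected counts left, was 130-fold lower (44.1 to 632), and Ccnjl, Arih2 and Kif26a were 23.5-fold, 22.7-fold and 19.2-fold lower. Arih2 lies on chromosome 9 within 1 Mb after Rhoa, where the median was below the other autosomes in both knock-in libraries against WT_vector.

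In this comparison 7 of 35 list medians lay above and 10 below the central 95% of random lists, and all 17 stayed outside on the same side after subtracting each chromosome's median. Desmosome and keratin genes had a median of 0.92 (percentile 100), and 5 of 11 members were 2-fold higher. Pkp2 differed by 1.63, Krt8 by 1.35, Dsc2 by 1.33 and Krt19 by 1.04. Epithelial adhesion genes had a median of 0.32 (percentile 100), with 5 of 27 members higher and 1 lower, Ildr1 at -2.61, while Cgn differed by 1.51 and Pard6b by 1.10. Transcription factors of epithelial-mesenchymal transition had a median of -0.72 (percentile 0) over the same 10 tested members. Id3 was at -2.75, Sox4 at -1.66, Twist1 at -1.41 and Id2 at 1.89. Mesenchymal markers had a median of 0.24 (percentile 98.86) and went both ways, with Vim at -2.62 and Cyr61, Serpine1 and Fn1 at 2.21, 1.62 and 1.60. Vim had 89.7, 125 and 8.37 normalised counts in the 3 libraries. Trophoblast stemness genes had a median of -0.62 (percentile 0), with 4 of 19 members 2-fold lower, namely Bmp4 at -1.65, Sox2 at -1.44, Esrrb at -1.11 and Cdx2 at -1.07. FGF and ERK feedback targets had a median of -0.85 (percentile 0), with Spry4 at -2.66, Ccnd1 at -1.76, Etv5 at -1.48 and Spred1 at -1.44. Cholesterol synthesis genes had a median of 0.31 (percentile 99.95), and 0 of 15 were 2-fold different. Histone deacetylase genes had a median of -0.08 (percentile 26.0), with Hdac7 at -1.43 besides Hdac6.

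The design also asks how far the hairpin cells stood from wild type. In KI4_HDAC6sh against WT_vector, 512 genes were higher and 283 lower, 67 and 81 of them by at least 4-fold. Higher genes made up 64.4% of these, and 53.4% under median-of-ratios scaling. The median of desmosome and keratin genes was 0.53 (percentile 99.89), of epithelial adhesion genes 0.39 (percentile 100), of mesenchymal markers 0.54 (percentile 99.98) and of trophoblast stemness genes -0.53 (percentile 0). Fn1 differed by 2.85 and Cldn6 was 2.65-fold higher (2.52 to 2.79). Chromosomes 1, 8 and 19 lay -0.49, -0.51 and 0.54 from the other autosomes, and Rhoa differed by -7.93. Fn1 lies on chromosome 1.

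Of the 543 genes higher in KI4_vector than in WT_vector, 194 were at least 2-fold lower again in KI4_HDAC6sh (35.7%, Clopper-Pearson 31.7 to 39.9), and 12 were at least 2-fold higher still. Of the 244 lower genes, 83 were at least 2-fold higher again (34.0%, 28.1 to 40.3), and 7 were lower still. These intervals treat genes as independent, which genes of the same 3 libraries are not, and cover no variation between cultures. Genes matched on expression made the same moves in 3.21% and 3.02%. Independent lists of these sizes would share 22.0 and 7.38 genes. Simulated unchanged libraries gave 0 such genes with counting noise alone and at a coefficient of variation of 0.1. At 0.2 they gave 5.19 and 13.0 genes, which were 7.05% of the higher and 17.7% of the lower genes simulated. At 0.4 they gave 302 and 437, more than observed, or 27.9% and 40.4%, of which the latter is above the 34.0% observed. Those libraries had 1082 higher and 1082 lower genes, above the 543 and 244 observed, so they differed more than the measured ones. With 1 KI4_vector library the shared library cannot be split, so part of the excess may come from it. By size of the first difference, the higher genes that moved back were led by Plxnd1, Fmr1nb, Tcf15, Fam111a, Ctsc, Rnf17, Trib2, Gpc4, Aim2 and Scin. Trib2 had 91.4, 1379 and 88.7 normalised counts and Rnf17 44.9, 790 and 47.7. The lower ones were led by Dnmt3l, Xlr5b, Xlr5a, Fabp3, Maoa, DXBay18, Zfp280c, Impact, Cdc42ep1 and Ptpn21. Fabp3, a fatty acid binding protein gene, had 4587, 221 and 1316 normalised counts and Ptpn21 601, 97.7 and 744. Counted over all these genes, including those that moved back, 203 of the higher and 86 of the lower were still at least 2-fold from WT_vector. Dnmt3l moved back but was still 35.7-fold lower than in WT_vector (28.1 to 45.9).

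**Figure D5:**
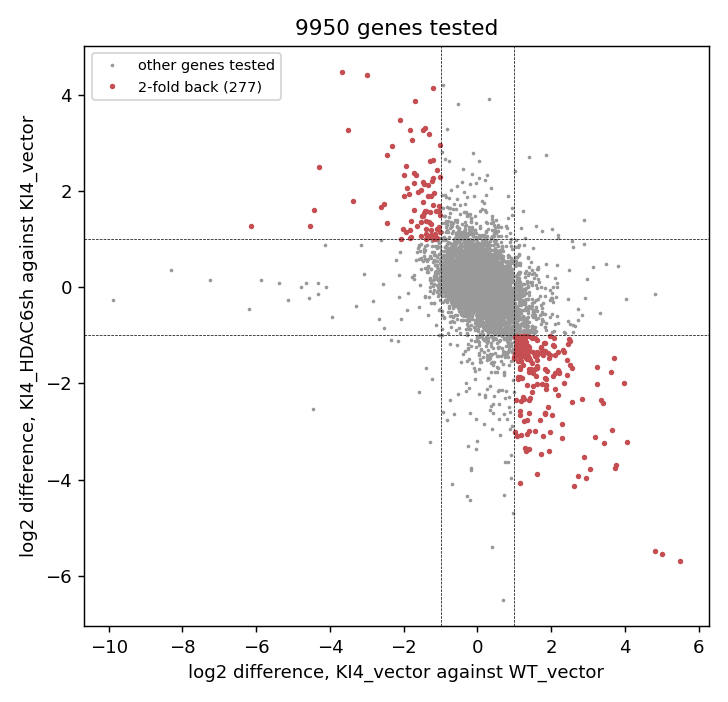
Log2 difference in KI4_HDAC6sh against KI4_vector (vertical) by that in KI4_vector against WT_vector (horizontal) for the 9950 genes tested, with dashed lines at 2-fold. The 277 red points are 2-fold different and at least 2-fold back, and both axes share KI4_vector, which tilts the cloud downward even with noise alone.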

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

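Chromosome-centred differences and results without chromosomes 1, 8, 9, 19, X and Y were chosen after seeing the data, and the other alternatives before. Across alternatives, 89 of the gene counts and shares stayed within 1.5 times the main count or within the Clopper-Pearson interval of the share over genes, and 31 did not. Of list medians, 1312 stayed inside the order-statistic interval of the list and 20 left it. That interval is the full range of the members where 8 or fewer were tested. Another 6 medians, which had lain outside the central 95% of random lists, changed sign. Some medians inside that range also changed sign and are counted among the 1312 or the 20. Values for named genes here include the added ppm, while their counting intervals do not. Of these values, 3197 lay inside the interval and 892 did not. The 892 include genes with 0 counts, which have no interval, and genes such as Plxnd1 whose main value already lay outside. They therefore do not count values moved by an alternative. Of list percentiles, 138 stayed inside the sampling interval of the random lists, 275 left it and 1 changed side. In the order higher and lower for KI4_vector against WT_vector, then KI4_HDAC6sh against KI4_vector, then KI4_HDAC6sh against WT_vector, a 1.5-fold threshold gave 1438, 883, 859, 846, 1441 and 936 genes and a 4-fold threshold 91, 48, 54, 119, 67 and 81. A filter at 20 ppm, which tests fewer genes, gave 263, 136, 158, 208, 230 and 143. Without a filter, which tests more, there were 873 higher and 373 lower in the first comparison, 655 lower in the second, and 799 and 440 in the last. With 5 ppm added, the counts of higher genes were 349, 188 and 283. Leaving out the chromosomes, which tests fewer genes, gave 139 lower, 177 higher and 172 lower genes in the 3 comparisons. The share of lower genes that moved back was 40.5% with 0.1 ppm added, and the share of higher genes 52.7% when the first difference had to be 4-fold; the cause was not tested.

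In KI4_HDAC6sh against KI4_vector, medians changed sign with the members tested. That of giant cell genes was 0.17 without a filter. That of blood and endothelial markers was 0.14 without a filter and 0.45 with the 20 ppm filter or without the chromosomes, where its percentile was 97.6. That of Wnt targets was 0.11 at 20 ppm and that of epithelial regulators -0.22 without the chromosomes. Without a filter, fibroblast marker medians were 0.48 in the first and -0.27 in the second comparison, and that of primitive endoderm markers -0.16 in the second. The latter was -0.95 with 0.1 ppm and -0.64 with 5 ppm added. The Y-linked list had medians of -9.17, 1.12 and -8.05 with 0.1 ppm, and -3.64 and -3.61 against WT_vector with 5 ppm, since its knock-in values are near 0. It had 0.16 in the second comparison with unscaled expected counts, and 0.00 against WT_vector after centring, where Eif2s3y stood at 1.77, both by construction. Ribosomal protein genes had medians of 0.089 and -0.035 in KI4_vector and KI4_HDAC6sh against WT_vector under median-of-ratios scaling, 0.11 and -0.0090 with TPM, 0.081 and -0.038 after centring, and -0.11 in the second comparison with unscaled expected counts; the cause was not tested. Of 46 list medians outside the central 95% of random lists, 40 stayed there on the same side with unmatched lists, 42 without unnamed gene models and 39 after centring. Without the chromosomes 35 of 42 did. Centring on whole chromosomes leaves segments such as those of chromosomes 2 and 11 in place. Those that did not with unmatched lists were desmosome and keratin genes in the first comparison, ribosomal protein genes in the first and second, and giant cell genes, Wnt targets and p53 targets in KI4_HDAC6sh against WT_vector. Depth limits the folds of genes with 0 counts in a library, which are given as bounds.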

Other observations

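The tests of genes on the shifted side, of the genes beside Rhoa, of the gain of Rhob and Rhoc in KI4_HDAC6sh and of each culture differing on its own, and the rule for long segments, were chosen only after the results were seen. Few markers of other lineages were tested. Fibroblast markers, of which 4 of 16 were tested, had medians of 1.38 and -1.17 in the first and second comparison (percentiles 99.64 and 0.64), led by Fbln1 at 2.11 and Col5a1 at -3.46. Pluripotency markers, with 4 tested, had 0.72 and -0.72, and Klf2 differed by 2.47 in the first. Giant cell genes, with 6 tested, had 0.65 and -0.63, with Scin at 3.61 and Kdr at 2.72. Spongiotrophoblast genes had 0.23 and 0.06, syncytiotrophoblast genes -0.28 and -0.08, primitive endoderm markers 0.44 and -0.87, and blood and endothelial markers 0.37 and -0.51. Basement membrane and integrin genes had 0.22 and 0.25, and 0.62 in KI4_HDAC6sh against WT_vector (percentile 100), with Lama1 at 2.59 and Nid1 at 2.34 in the first comparison. Epithelial regulators had -0.17 and 0.27, with Tfcp2l1 at 1.75 and Cited1 at 1.63. As given above, the second values of giant cell genes, blood and endothelial markers and epithelial regulators changed sign with the members tested. Fibroblast medians were smaller in size without a filter.

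Among signalling genes, the MAP3K4 pathway list had medians of 0.26 and 0.08, with Gadd45a, a known activator of the kinase, at 2.38 and Map2k6 at 2.18 in the first comparison. Immediate early genes had 0.05 and 0.09, TGF-beta targets 0.26 and 0.08, and Wnt targets 0.05 and -0.37, where the values of 0.05 and the 0.08 of TGF-beta targets took the other sign under another scaling or unit. Axin2 differed by -3.07 in the second. Targets of p53 had 0.36 and 0.08, led by Eda2r at 2.18 and -2.24, which lies in the X segment from 90.6 to 131 Mb. Interferon response genes had 0.14 and 0.38, tubulin and actin genes 0.17 and 0.34 with Msn, in the same X segment, at 1.89 and -1.73, and heat shock genes -0.25 and 0.09 with Hspa1a, whose reads are uncertain because of its near-identical copy, at -3.30 in the second. Hypoxia and glycolysis genes had 0.15 in the second comparison, unfolded protein genes 0.15, proteases of invasion -0.16 and proliferation genes 0.00, whose sign depended on the scaling. Histone deacetylases had 0.19 in the first, acetyltransferases and readers -0.11 and -0.07, and chromatin complexes -0.04 and 0.06. Imprinted genes had -0.14 and 0.06, the latter below 0 with FPKM, with Gatm at 2.89, Impact at -2.62 and 1.67, Phlda2 at -2.60 and Peg3 at 1.92 in the second. Igf2, the neighbour of H19, was named after its values were seen and had 153308, 200931 and 209744 normalised counts in the 3 libraries. Ribosomal protein genes had 0.19 and -0.15, reference genes 0.10 and -0.01, both of the other sign under median-of-ratios scaling, and the Y-linked list -5.87 and 0.16.

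Chromosomes 1 and 8 in KI4_vector against WT_vector and chromosome 19 in KI4_HDAC6sh against KI4_vector were shifted as a whole, and the tests were run on these comparisons alone. GC content and gene length do not account for the whole of it, since the smallest of the 3 shifts was -0.46 after subtracting medians of GC and length bins. A few genes would move a chromosome's median little in any case. At least 84.2% of each chromosome's genes in these comparisons lay on the shifted side, which restates the shift. A candidate explanation is a difference in copy number between the cultures. Both parts of each chromosome, split at the middle gene, were shifted the same way, with -0.45 the smallest in size. With at least 84.2% of genes on 1 side, the shared direction of the parts was fixed and lends this no weight. Their sizes show only that the shift was not confined to 1 part. Copy number remains a hypothesis without DNA data. Whether such a difference has anything to do with the allele or the hairpin cannot be read from 1 culture each.

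Rhoa, Tcta, Amt and Nicn1 were lost together in both knock-in libraries. Reads counted to the related genes Rhob and Rhoc, named as such outside the naming rule, do not account for the whole loss of Rhoa. Their joint gain was 8.39% of the Rhoa level of WT_vector in KI4_vector (95% counting interval 5.30 to 11.5) and 24.5% in KI4_HDAC6sh (21.3 to 27.7). An account by them would need at least 50%. The bound set for arguing against it was lower. It lies inside the interval of the 8.39% and below the 24.5%, so a part is not excluded. The joint gain nets opposite moves. In WT_vector, KI4_vector and KI4_HDAC6sh, Rhob had 748, 1556 and 2230 normalised counts and Rhoc 1980, 1550 and 1602. Rhoa had 4503 in WT_vector. A candidate explanation is loss of this segment from both chromosomes inside a longer segment lost from 1. The values were mixed. The 20 tested genes within 1 Mb after it had medians of -0.86 in KI4_vector and -0.85 in KI4_HDAC6sh from the other autosomes. Both are against WT_vector and are what such a loss would give. The 23 genes before it had -0.15 in KI4_vector, in the range set as arguing against it, and -0.44 in KI4_HDAC6sh, in neither range. The -0.15 mixes unlike genes and cannot decide. From Rbm6 to Dag1, nearest to it, the tested genes differed by -0.97, -0.12, -1.22, -1.06, -0.48, 0.44, -0.52 and -1.44 in KI4_vector. Farther off on that side, Tmem115 differed by -0.81 and Sema3f by 0.64. Past the 1 Mb after the lost genes, a stretch read only after the test, tested genes from 3000002C10Rik to Setd2 were all lower. They differed by -0.48 to -1.17 in KI4_vector and by -0.07 to -1.23 in KI4_HDAC6sh, both against WT_vector. The next tested gene, Nbeal2, differed by 1.29 and 0.64. The candidate stays open, because the longer segment need not reach 1 Mb on both sides, and whether the loss came with the allele cannot be read from these cultures.

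Genes that moved back in KI4_HDAC6sh may reflect the hairpin, noise in the shared library or the KI4_vector culture itself. Counting noise alone does not account for the 277 observed, since simulated unchanged libraries then gave 0 such genes. Those libraries had 0 genes 2-fold different in the first comparison, so none could move back, and the other explanations are left as they were. At a coefficient of variation of 0.2 they gave 18.15, or 6.55% of the 277. At 0.4 they gave 739, but also 1082 higher and 1082 lower genes in the first comparison, against 543 and 244 observed. That setting differs more than these libraries do, so its 739 cannot be set against the 277. No value between 0.2 and 0.4 was simulated, so noise beyond counting stays open. KI4_vector stood 2-fold apart from both others at 277 genes, WT_vector at 289, among them genes such as Rhoa, Ddx3y and H19 where both knock-in libraries differ from it, and KI4_HDAC6sh at 282, so the number for KI4_vector was 0.958 times the larger of the others. The order of these numbers was not kept, since KI4_vector had 258 and WT_vector 239 after chromosome centring, and KI4_vector had 178 and KI4_HDAC6sh 173 without chromosomes 1, 8, 9, 19, X and Y. The variance of the differences (log2 squared) that belonged to 1 library alone was 0.249 for WT_vector, 0.169 for KI4_vector and 0.196 for KI4_HDAC6sh, and a reversal by loss of Hdac6 stays open beside differences of the KI4_vector culture.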
